A study of Mus musculus with 15 samples.

How the data were processed

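The data were bulk RNA-seq of mouse cells, 15 libraries in 5 groups of 3, read from 1 table of 17030 genes. Per the labels' protocols, total RNA was taken up in TRIzol, treated with DNase, selected with oligo(dT) and made into libraries with a BGI Optimal Dual-mode mRNA kit and random hexamers. The submitters' processing notes name HISAT2 and Bowtie2, whose versions are not given in the sources used here. They also name RSEM 1.3.1, DESeq2 1.4.5 and the genome build GRCm38.p6. Which tool did which step, the gene annotation and the strand setting are not given in the sources used here.

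Each library had 3 columns in the table. The estimated counts were made by the authors and not normalised, per the file headers, which call them read counts. Their unit was read from the values, of which 94.4% to 96.0% per library were whole numbers and the rest carried decimals. The FPKM values (reads scaled by transcript length and library total) were made by the authors, per the file headers. TPM values were likewise computed by the authors, per the file headers, and were used here only for an alternative scaling. The table also held 15 columns of averages, which were not used here. No sample column was left without a match to the labels. Symbols that a spreadsheet had turned into dates were restored from the gene identifiers for 25 genes. Of 17030 identifiers, 16978 matched the RefSeq annotation of GRCm38.p6, which gave the coordinates of whole genes.

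The test written before the data were examined assumed that the table held FPKM alone and was limma on log2(FPKM + 1). Because estimated counts were present, edgeR's quasi-likelihood test on the rounded counts was used in its place, and the limma fit was kept as an alternative. The 5 comparisons, the fixed gene lists, the rule for named genes, the low-value filter and most alternatives were set before the data were examined.

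Genes were tested if they reached an FPKM of 1 in at least 3 of the 15 libraries, which kept 11793 genes and left out 5237. All 15 libraries went into 1 model with a mean per group, which left 10 residual degrees of freedom, with TMM normalisation, a two-sided test and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Levels are given as mean FPKM ± SD of 3 libraries, and changes as log2 ratios of the model with their SE. The ratio of FPKM levels and the modelled change therefore differ by the scaling. They can also differ by the transcript length that FPKM divides by, where it is not the same in each library. TMM takes most genes as unaltered between libraries, and every change is relative to that. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. Simulated counts (11793 genes) gave the CAR libraries the control-CAR mean levels, with known changes in some genes. Outside the S phase list, only genes with at least 10 expected counts were altered. Of these, the test recovered 74.6% of genes changed 1.5-fold, 95.5% of those changed 2-fold and all 66 changed 4-fold. It called 8 of the 11573 genes left alone. For the control-CAR and Hoxb8 macrophage libraries, both given the Hoxb8 macrophage means, the same number of simulated genes gave 80.6%, 95.5% and 95.5%. There, 9 of 11573 genes left alone were called. Most genes were unaltered in both simulations, so they do not measure error rates where most genes differ.

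Gene lists were tested with camera at a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2, against all other tested genes. Lists with at least 5 tested members entered this test, which were 33 of 37, and the adjusted p was taken over those 33. The same test with an estimated correlation, and fry, were run beside it. In the simulations the S phase list was raised 2-fold. There, camera called 0 other lists for CAR against control-CAR and 1 other list for control-CAR against Hoxb8 macrophages. Not tested as lists were the erythroid list and the T and NK cell list, with 2 tested members each, the mitochondrially encoded list, with 0 members in the table, and the sex chromosome list, with 0 tested members.

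The genes named for a comparison followed a rule with 3 parts. The rule took the 8 largest rises and 8 largest falls on the log2(FPKM + 1) scale among called genes, with no overlap between the 3 and 3 libraries and at least 10 FPKM in the higher group. Symbols that began with Gm and a digit, ended in Rik or were bare identifiers were passed over. The rule then took up to 4 members of each list with the largest absolute change among called members. A fixed set of myeloid, activation and division genes was the last part. Genes outside the rule are said, where they appear, to have been chosen after their values were seen. The results of 2 single genes are not reported here.

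The depth was 16962834 to 19221685 estimated counts per library. A gene with a count of 0 was taken to have up to 3 counts per library, 0.114 to 0.208 CPM (counts scaled by the effective library total), and a fold against a group at 0 in all 3 libraries is given as a lower bound from that floor. Such floors cover counting error only. Against a group with 1 to 3 counts in all, levels alone are given.

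Alternatives covered other scalings (FPKM, TPM, upper quartile, quantile), pseudocounts of 0.1 and 5 on the log scale, no low-value filter and a filter at FPKM 5, a fit of only the 6 libraries compared, a replicate block, a variance model without trend, a 2-fold minimum and leaving out each library. DESeq2, its size factors in edgeR, and library totals without TMM were added after the data were seen. The labels give no batch. Counts of genes from multi-copy families (the stefin A cluster of Stfa, Csta and Cstdc genes, Hmga1b, Tgtp2, Tpsb2, Hspa1a with Hspa1b, Bcl2a1a with its copies, Selenbp1) are uncertain, because reads can be shared between near-identical copies. Reads of a gene and an antisense or overlapping partner could not be told apart either, since the strand setting is not given in the sources used here.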

Results

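Messenger RNA was sequenced from mouse bone marrow cells in 15 libraries, 3 in each of 5 groups. Progenitor cells and Hoxb8 macrophages were wild type and untreated, and so were BMDM, macrophages from bone marrow. The other two groups were macrophages labelled as CAR, with CAR treatment, and as control-CAR. CAR is the usual short form of chimeric antigen receptor, an engineered receptor that points an immune cell at a chosen antigen. Hoxb8 is a homeobox transcription factor whose forced expression is a common way to keep myeloid progenitors dividing in culture. The total estimated count ran from 16962834 to 18049539 in the control-CAR libraries and from 18752383 to 19221685 in the BMDM libraries, with the other groups between. A count above 0 was found for 14758 ± 41.9 genes in the CAR libraries (SD, n = 3), 14428 ± 88.6 in BMDM, 13052 ± 43.3 in Hoxb8 macrophages, 13022 ± 112 in control-CAR macrophages and 12560 ± 34.6 in progenitor cells. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

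The 10 most abundant genes held 3.89% ± 0.0915 of the counts in progenitor cells (SD, n = 3) and from 8.79% ± 0.0295 in CAR macrophages to 12.4% ± 0.180 in Hoxb8 macrophages. Fth1, the ferritin heavy chain that stores iron, alone held 3.73% ± 0.224 in Hoxb8 macrophages and 0.0766% ± 0.00623 in progenitor cells, a gene chosen after its values were seen for this share. Changes also depended on the scaling and test, and why the groups scaled apart was not tested. Library totals leave out the TMM factors, which were 0.824 to 0.829 in Hoxb8 macrophages and 1.46 to 1.47 in progenitor cells. Library totals in place of TMM moved the median log2 change of all tested genes by 0.31 for CAR against control-CAR, -0.74 for Hoxb8 macrophages against progenitors, -0.17 for Hoxb8 macrophages against BMDM and -0.64 for BMDM against progenitors. TPM moved the same medians by 0.45, -0.91, -0.27 and -0.71, FPKM by 0.23, -0.62, -0.11 and -0.58, and quantile normalisation by -0.16, -0.14, 0.12 and -0.32. The upper quartile moved them by 0.077, -0.13, -0.042 and -0.16. Here and below, the FPKM, TPM and quantile alternatives are limma fits on log values, so the test differs from edgeR on counts as well as the scaling. Changes below are relative to TMM.

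Control-CAR and Hoxb8 macrophages had nearly the same profile, with a correlation of 0.997 across genes between the group means. BMDM correlated with control-CAR macrophages at 0.866, with CAR macrophages at 0.807 and with progenitor cells at 0.583, and CAR with control-CAR macrophages at 0.80. These correlations are across genes, and genes are not independent replicates. Within groups, the pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom from 1.40 for CAR replicates 1 and 2 to 21.3 for BMDM replicates 1 and 3.

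**Figure D1:**
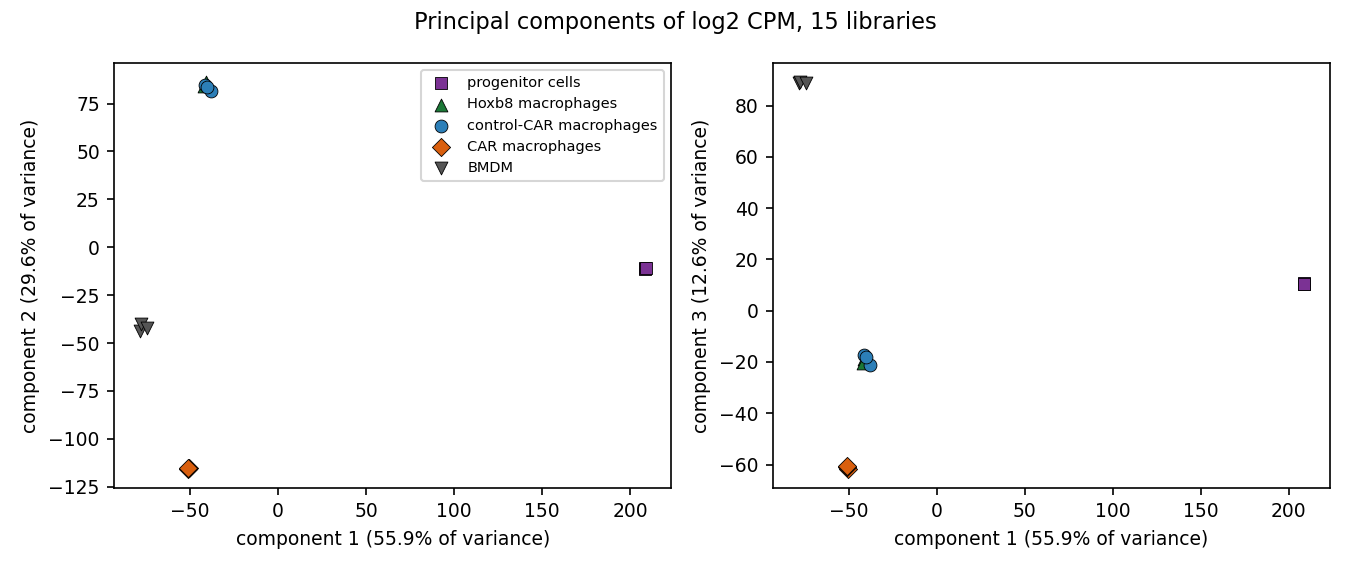
Principal components of log2 CPM, 1 point per library, with component 1 (55.9% of the variance) on the horizontal axes and components 2 (29.6%) and 3 (12.6%) on the vertical axes. The 3 libraries of each group lie together, and the control-CAR and Hoxb8 macrophage libraries overlap.

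The series describes its design as CAR-treated cells against a control, which is the comparison of CAR with control-CAR macrophages. Arg1, the arginase of alternatively activated macrophages, fell 383-fold, from 1499 ± 6.80 FPKM in control-CAR macrophages to 4.81 ± 0.583 in CAR macrophages (SD, n = 3 each), a log2 change of -8.58 (SE 0.21). Ubd, a ubiquitin-like protein induced by interferon gamma and TNF, rose from 0.51 ± 0.360 to 364 ± 6.92 FPKM, a log2 change of 9.14 (SE 0.16). Penk, which encodes the enkephalin precursor, stood at 397 ± 6.90 FPKM in CAR and 0.04 ± 0.0693 in control-CAR macrophages. Hoxb8 fell from 61.9 ± 1.0 to 8.86 ± 0.457 FPKM, a log2 change of -3.11 (SE 0.06). Esr1, the estrogen receptor gene, chosen after its values were seen, went with it from 148 to 17.1 FPKM, a log2 change of -3.28 (SE 0.08).

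Other genes with the largest rises were Hmga1b (229 ± 2.27 against 0.24 ± 0.214 FPKM), the interferon-induced GTPase gene Tgtp2 (214 ± 0.872 against 0.733 ± 0.0987), Tm4sf1 (130 ± 2.31 against 0.347 ± 0.104) and the mast cell IgE receptor chain Fcer1a (97.3 ± 2.43 against 0.0267 ± 0.0462). The homeobox gene Rhox5 reached 103 ± 0.667 FPKM and the neutrophil chemokine gene Cxcl1 97.5 ± 4.33 FPKM. Both had a count of 0 in the 3 control-CAR libraries, so they were at least 272-fold and at least 298-fold higher. The largest falls besides Arg1 included S100a9, a calcium-binding protein of neutrophils and monocytes (2.33 ± 0.561 against 406 ± 27.5 FPKM, log2 change -7.70, SE 0.42), the collagenase gene Mmp13 (4.71 ± 0.318 against 327 ± 24.1, log2 change -6.42, SE 0.28), Selenbp1 (log2 change -6.92, SE 0.14) and Pld4 (log2 change -5.77, SE 0.14). The stefin A family genes Stfa2l1, Cstdc5 and Stfa2 fell as well, with log2 changes of -8.19, -7.17 and -6.39, and their counts are uncertain because the copies share sequence. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p from 4.6e-20 for Tgtp2 to 4.3e-11 for Stfa2l1 over the 16 genes with the largest changes. In build GRCm38.p6, Penk (gene ID 18619) lies on chromosome 4 from 4133536 to 4138815, Ubd (24108) on chromosome 17 from 37193892 to 37196101, and Arg1 (11846) on chromosome 10 from 24915207 to 24927470. Hoxb8 (15416) lies on chromosome 11 from 96279401 to 96285325 and Rhox5 (18617) on chromosome X from 37754608 to 37808878.

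Several macrophage genes were lower but still abundant in the CAR libraries. Lyz2, the macrophage lysozyme, fell from 5027 ± 172 to 612 ± 6.11 FPKM (log2 change -3.34, SE 0.07). Csf1r, the receptor for the macrophage growth factor CSF1, fell from 303 ± 6.24 to 109 ± 0.948 FPKM (log2 change -1.78, SE 0.08). Adgre1, which encodes the macrophage surface protein F4/80, fell from 1131 ± 37.2 to 811 ± 9.96 FPKM (log2 change -0.79, SE 0.10), and Itgam fell by 1.11 on the log2 scale (SE 0.08). For Cd68 the log2 change was -0.34 (SE 0.11), and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.00722, which became 0.0550 without control-CAR replicate 2. The direction of Cd68 turned under TPM (log2 change 0.22) and after quantile normalisation (0.084). Of 24 tested members of the macrophage identity list, 7 rose and 13 fell, and camera did not call the list (adjusted p = 0.150). Among them, Gpnmb, a membrane glycoprotein of lipid-laden macrophages, rose from 26.5 ± 3.31 to 1479 ± 40.6 FPKM (log2 change 5.49, SE 0.10), while Pparg and Siglec1 fell, with log2 changes of -5.89 (SE 0.22) and -3.17 (SE 0.21).

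Cell division genes were higher in the CAR libraries, in which mast cell and basophil genes and 5 of 7 fibroblast genes rose too, and which cells carried them was not tested. All 20 tested members of the S phase list rose (camera adjusted p = 3.4e-08), and this call held at an adjusted p = 0.0146 with an estimated correlation. Rrm2, a subunit of the reductase that makes DNA precursors, went from 0.463 ± 0.129 to 64.0 ± 1.65 FPKM (log2 change 6.79, SE 0.13), and the replication helicase subunit Mcm7 from 1.66 ± 0.320 to 50.4 ± 1.20 FPKM (log2 change 4.61, SE 0.09). All 20 members of the G2 and M phase list rose too (camera adjusted p = 3.1e-08, adjusted p = 0.290 with an estimated correlation). Cdc20, an activator of the mitotic ubiquitin ligase, went from 0.357 ± 0.166 to 47.6 ± 2.80 FPKM (log2 change 6.73, SE 0.14), and the proliferation marker Mki67 from 6.20 ± 0.227 to 23.8 ± 0.260 FPKM (log2 change 1.64, SE 0.12).

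Interferon and MHC class I genes moved the same way. Of 21 tested members of the type I interferon list, 18 rose and 1 fell (camera adjusted p = 1.1e-04, adjusted p = 0.290 with an estimated correlation). Ifit2 rose from 0.38 ± 0.0265 to 14.6 ± 0.483 FPKM (log2 change 4.96, SE 0.20) and Oasl2, a relative of the antiviral oligoadenylate synthetases, from 3.61 ± 0.276 to 46.6 ± 1.27 FPKM (log2 change 3.33, SE 0.08). The MHC class I list had 10 rises and 3 falls among 14 tested members (camera adjusted p = 0.00840, adjusted p = 0.461 with an estimated correlation). Nlrc5, the transactivator of MHC class I genes, rose from 0.103 ± 0.0208 to 27.7 ± 0.361 FPKM (log2 change 7.77, SE 0.12), and the peptide transporter gene Tap1 from 23.4 ± 1.58 to 237 ± 2.38 FPKM (log2 change 3.04, SE 0.07). The MHC class II list had 5 rises and 6 falls among 13 tested members (6 and 5 under FPKM, TPM, the upper quartile and library totals) and was not called (camera adjusted p = 0.685).

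The glycolysis and hypoxia list fell in the CAR libraries, with 23 of 24 tested members lower and 1 higher (camera adjusted p = 8.7e-09, adjusted p = 0.290 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, fell from 709 ± 23.2 to 67.2 ± 1.55 FPKM (log2 change -3.71, SE 0.08), and Ankrd37 from 39.1 ± 1.76 to 3.20 ± 0.506 FPKM (log2 change -3.90, SE 0.17). The neutrophil list fell as well, with 15 of 17 tested members lower and 1 higher (camera adjusted p = 1.6e-04, adjusted p = 0.290 with an estimated correlation). Csf3r, the receptor for the granulocyte growth factor G-CSF, fell from 37.9 ± 0.364 to 5.21 ± 0.455 FPKM (log2 change -3.21, SE 0.06).

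Inflammatory genes split. In the pro-inflammatory list 17 of 24 tested members fell and 5 rose (camera adjusted p = 0.0215, adjusted p = 0.290 with an estimated correlation, and 0.353 after quantile normalisation). The median log2 change of this list was -1.05 and the mean 0.19. Camera called it downward, while fry, a test of the list by itself, called it upward (adjusted p = 1.2e-04). Why the 2 tests differed was not tested. Il1b, the inflammatory cytokine interleukin 1 beta, fell from 6335 ± 310 to 2924 ± 102 FPKM (log2 change -1.42, SE 0.07), Il6 by 0.78 (SE 0.13), Nos2, the inducible nitric oxide synthase, by 0.56 (SE 0.09) and the costimulatory gene Cd80 by 1.47 (SE 0.06) on the log2 scale. Under TPM the log2 changes of Il6 and Nos2 were -0.23 and -0.011 and did not pass the threshold. Those that rose included Cd86, another costimulatory gene (7.33 ± 0.599 against 0.163 ± 0.0651 FPKM, log2 change 5.19, SE 0.21), the costimulatory receptor Cd40 (log2 change 5.20, SE 0.15) and the interferon regulatory factor Irf1 (368 ± 6.78 against 28.5 ± 1.64 FPKM, log2 change 3.39, SE 0.07). Tnf had a log2 change of 0.14 (SE 0.13) and did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.338), but it was called higher under FPKM (log2 change 0.46), TPM (0.70), library totals (0.46) and quantile normalisation (0.38).

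Of 26 tested phagocytosis genes, 20 fell and 5 rose (camera adjusted p = 0.0109, adjusted p = 0.563 with an estimated correlation). Its median log2 change was -0.73 and its mean 0.39, with camera on the side of the median and fry, not called (adjusted p = 0.854), on that of the mean. The scavenger receptor gene Marco fell from 325 ± 49.3 to 13 ± 0.780 FPKM (log2 change -4.95, SE 0.17). Axl, a receptor for the uptake of dying cells, had 78.1 ± 1.95 FPKM in CAR macrophages and a count of 0 in the control-CAR libraries, at least 1440-fold higher. Of 28 tested lysosome genes, 18 fell and 4 rose (camera adjusted p = 0.0215, adjusted p = 0.742 with an estimated correlation). This call was lost under FPKM (adjusted p = 0.0792), TPM (0.230) and library totals (0.0743), and turned upward without a call under quantile normalisation (0.732). Under TPM more of these genes rose (17) than fell (7). The cathepsin D gene Ctsd fell from 10383 ± 973 to 4968 ± 108 FPKM (log2 change -1.37, SE 0.09, but 0.27 after quantile normalisation) and the cathepsin L gene Ctsl rose from 63.8 ± 2.96 to 620 ± 8.81 FPKM (log2 change 2.98, SE 0.08).

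Of the lists of other cell types, camera called only that of mast cells and basophils upward in the CAR libraries. All 9 tested members of the mast cell and basophil list rose (camera adjusted p = 2.0e-04, adjusted p = 0.182 with an estimated correlation). Cpa3, the mast cell carboxypeptidase, rose from 28.2 ± 6.89 to 2221 ± 99.0 FPKM (log2 change 6.02, SE 0.14), against 1284 ± 56.6 FPKM in progenitor cells. The mast cell chymase gene Cma1 stood at 90.2 ± 3.34 against 0.0733 ± 0.0751 FPKM, and Ms4a2, the beta chain of the IgE receptor, rose by 6.21 on the log2 scale (SE 0.28). Kit, the stem cell factor receptor of progenitors and mast cells, was 4.71 ± 0.251 against 4.02 ± 0.327 FPKM and did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (log2 change -0.078, SE 0.11, adjusted p = 0.522). The log2 change of Kit was 0.40 under TPM and -0.38 after quantile normalisation, each past the threshold. Cd34, a marker of progenitors, mast cells and endothelium, rose from 1.92 ± 0.157 to 40.8 ± 2.65 FPKM (log2 change 4.11, SE 0.10). In the fibroblast list 5 of 7 tested members rose and 1 fell (camera adjusted p = 0.0595), among them the collagen gene Col1a2 (23.9 ± 0.700 against 0.01 ± 0.01 FPKM) and the matrix protein gene Sparc (16.4 ± 0.447 against 0 FPKM, at least 162-fold higher). In the epithelial and colon tumour list 3 of 5 rose and 1 fell (camera adjusted p = 0.192), with the keratin gene Krt20 at 5.46 ± 0.0458 against 0 FPKM, at least 42.5-fold higher. The myeloid progenitor list had 10 rises and 5 falls among 21 tested members (camera adjusted p = 0.291), with the neutrophil protease gene Ctsg at 113 ± 4.62 against 2.79 ± 0.665 FPKM. Both tested erythroid genes rose, Hbb-bt to 62.0 ± 4.91 from 2.20 ± 0.745 FPKM and Gata1 to 6.54 ± 0.774 from 0.207 ± 0.135 FPKM, and of the 2 tested T and NK cell genes Il7r rose (log2 change 0.67, SE 0.07). The megakaryocyte list had 2 rises and 3 falls among 6 (camera adjusted p = 0.772), the osteoclast list 4 rises and 3 falls among 7 (camera adjusted p = 0.685), and of the 5 tested B cell genes 0 were called (camera adjusted p = 0.819). The mitochondrially encoded and sex chromosome lists were not analysed here.

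In all, 9280 of 11793 genes (78.7%) passed edgeR's quasi-likelihood test between CAR and control-CAR macrophages, 4946 higher and 4334 lower, of which 3739 changed at least 2-fold. The FPKM values of the 3 and 3 libraries, which carry no TMM scaling, did not overlap for 82.1% of genes, where chance gives 10%. Here and below, a scaling offset common to all genes can raise this share. The split into higher and lower depended on the scaling and test and was 6713 and 2770 under FPKM, 8018 and 1933 under TPM, and 6722 and 2770 under library totals, and it turned to 4212 and 5306 after quantile normalisation. Of 33 lists, 10 were called, 5 up and 5 down, and only the S phase call held with an estimated correlation. For each of the 35 lists with tested members the number of members called was the same adjusted over the list alone as over all genes.

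**Figure D2:**
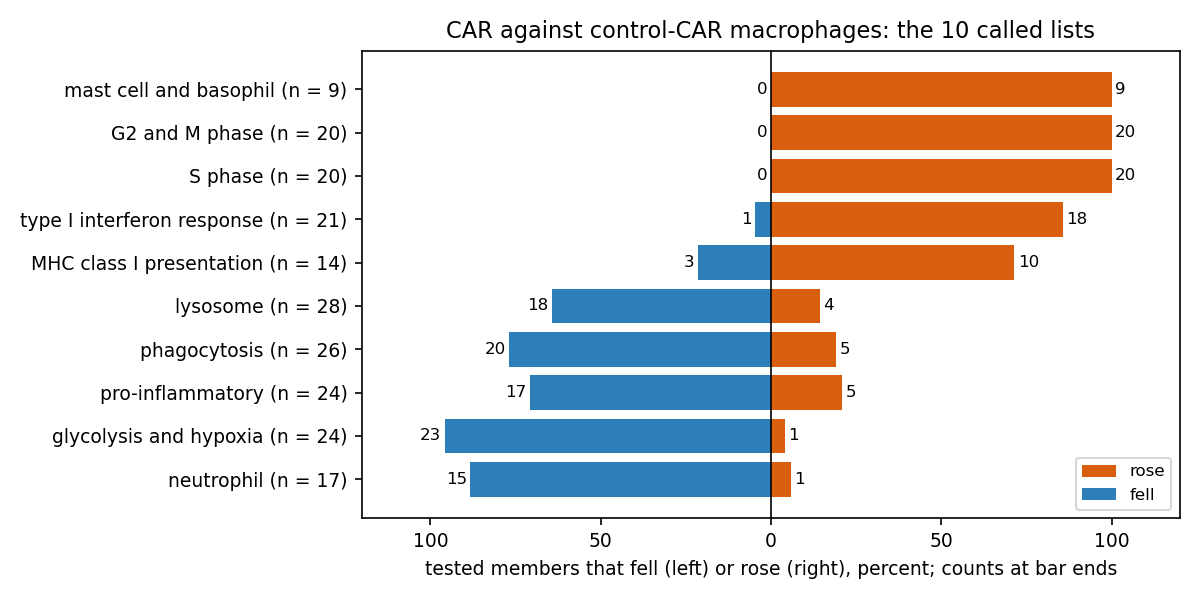
Percent of tested members that rose (right) or fell (left) in CAR against control-CAR macrophages, for the 10 lists called by camera at the preset correlation, with the numbers of members at the bar ends. All 20 S phase and all 20 G2 and M phase genes rose, and 23 of 24 glycolysis and hypoxia genes fell.

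**Figure D3:**
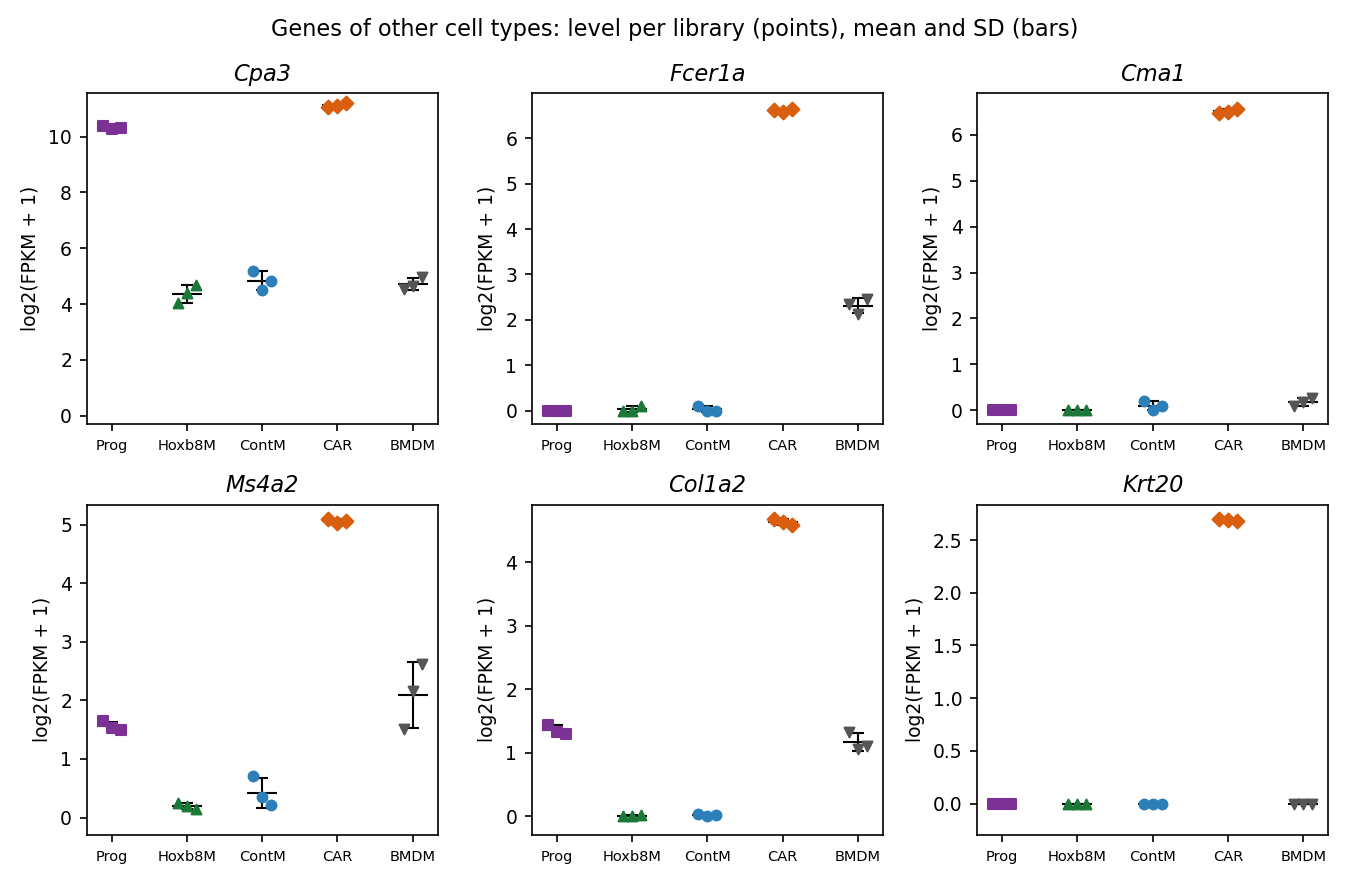
Levels of 6 genes of other cell types in each library as log2(FPKM + 1), with a point per library and the mean and SD of 3 libraries per group. Cpa3 lies highest in the CAR libraries (2221 FPKM) and next in progenitor cells (1284 FPKM), and Col1a2 reaches 23.9 FPKM in the CAR libraries.

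Hoxb8 macrophages were compared with progenitor cells. The macrophages, labelled untreated, held the activation genes Nos2 and Il6 at 1981 and 470 FPKM. Differentiation could not be told apart from activation or culture conditions in this comparison. Adgre1 rose from 0.49 to 1070 ± 56.0 FPKM (SD, n = 3), a log2 change of 11.92 (SE 0.17), and Csf1r from 0.497 to 296 ± 12.3 FPKM, a log2 change of 10.04 (SE 0.13). Kit fell from 113 ± 1.31 to 4.57 ± 0.668 FPKM (log2 change -3.80, SE 0.10), and Cd34 from 110 to 1.87 FPKM (log2 change -5.05, SE 0.10). Ctsg, a protease of granulocyte precursors, fell 605-fold, from 1976 ± 12.7 to 1.82 ± 0.0321 FPKM (log2 change -9.24, SE 0.16). Hoxb8 itself was 122 ± 0.830 FPKM in progenitors and 51.2 ± 2.04 FPKM in macrophages, a log2 change of -0.42 (SE 0.05), and Esr1, again chosen after its values were seen, had a log2 change of -0.56 (SE 0.07).

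The 8 largest rises were as follows. The chemokine gene Ccl5 reached 18900 ± 1643 FPKM against 0.17 in progenitors and the cytokine gene Il1b 6421 ± 181 against 0.0833 FPKM. Cxcl3, a chemokine gene, reached 4645 ± 445 FPKM and Hamp, the iron hormone hepcidin, 3828 FPKM, each with a count of 0 in the progenitor libraries, at least 34575-fold and at least 4410-fold higher. Saa3, an acute phase protein gene, stood at 3896 against 0.04 FPKM. The stefin genes Cstdc4, Stfa3 and Csta2 stood at 23044 ± 3144, 8537 and 8027 FPKM in macrophages, and at 0.18, 0 and 0.09 FPKM in progenitors. The largest falls included Ms4a3, a marker of granulocyte and monocyte progenitors (1.12 against 684 FPKM, log2 change -8.40, SE 0.19), the progenitor transcription factor Myb (0.603 against 254 FPKM, log2 change -7.83, SE 0.17), Muc13, Ccr2 and Stmn1, a tubulin regulator of dividing cells (5.03 against 717 FPKM, log2 change -6.31, SE 0.08).

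Macrophage and inflammatory lists rose together. In macrophage identity 22 of 24 tested members rose and 1 fell (camera adjusted p = 1.5e-06, adjusted p = 0.0913 with an estimated correlation), with the lipid receptor gene Trem2 at 273 ± 10.2 against 0.0233 FPKM. In the pro-inflammatory list 23 of 24 rose (camera adjusted p = 2.4e-09), and this held at an adjusted p = 0.0151 with an estimated correlation. Nos2 reached 1981 ± 178 FPKM from a count of 0, at least 80010-fold higher. All 16 NF-kB genes rose (camera adjusted p = 1.3e-07, adjusted p = 0.0552 with an estimated correlation), among them the inhibitor gene Nfkbia (569 ± 41.3 against 12.4 ± 1.24 FPKM). In alternative activation 17 of 19 rose and 1 fell (camera adjusted p = 7.6e-06, adjusted p = 0.0552 with an estimated correlation), with Arg1 at 1294 ± 305 FPKM from a count of 0, at least 15847-fold higher. The chemokine list had 11 rises among 12 (camera adjusted p = 1.7e-05, adjusted p = 0.0552 with an estimated correlation). The neutrophil list had 17 rises among 17 (camera adjusted p = 1.0e-05, adjusted p = 0.113 with an estimated correlation), with the iron-binding lipocalin gene Lcn2 at 14579 ± 990 against 12.5 ± 1.26 FPKM (log2 change 11.03, SE 0.11). Of 21 interferon genes all rose (camera adjusted p = 7.9e-06, adjusted p = 0.0890 with an estimated correlation), with the chemokine gene Cxcl10 at 114 ± 26.0 against 0.12 ± 0.111 FPKM.

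Glycolysis and degradative lists rose as well. The glycolysis and hypoxia list had 24 rises among 24 members (camera adjusted p = 8.8e-09, adjusted p = 0.113 with an estimated correlation), with the lipid droplet gene Hilpda at 1372 ± 61.6 against 12.8 ± 1.13 FPKM (log2 change 7.59, SE 0.08). The lysosome list had 27 rises and 0 falls among 28 (camera adjusted p = 1.9e-07, adjusted p = 0.302 with an estimated correlation), and 27 rises and 1 fall adjusted over the list alone. Ctsd rose from 447 ± 14.4 to 10876 ± 366 FPKM (log2 change 5.44, SE 0.10). All 14 matrix protease genes rose (camera adjusted p = 1.0e-05, adjusted p = 0.0913 with an estimated correlation), with the macrophage elastase gene Mmp12 at 1116 ± 299 against 0.04 FPKM. Of 15 NRF2 and iron genes 13 rose and 2 fell (camera adjusted p = 2.0e-04, adjusted p = 0.128 with an estimated correlation), with the heme oxygenase gene Hmox1 at 3244 ± 154 against 11.9 ± 1.24 FPKM (log2 change 8.92, SE 0.09). The phagocytosis list had 20 rises and 4 falls among 26 (camera adjusted p = 9.2e-04, adjusted p = 0.322 with an estimated correlation). In the inhibitory and checkpoint list 11 of 13 rose and 1 fell (camera adjusted p = 9.2e-04), which held at an adjusted p = 0.0332 with an estimated correlation. Cd274, the ligand of the checkpoint receptor PD-1, rose from 7.93 ± 0.749 to 375 ± 21.7 FPKM (log2 change 6.39, SE 0.08). The dendritic cell list had 8 rises and 1 fall (camera adjusted p = 0.0209, adjusted p = 0.0913 with an estimated correlation) and the osteoclast list 6 rises and 1 fall (camera adjusted p = 0.0210, adjusted p = 0.219 with an estimated correlation). In the apoptosis list 19 of 26 rose and 5 fell (camera adjusted p = 0.00878, adjusted p = 0.0552 with an estimated correlation). Under FPKM, TPM and library totals more of its members fell (13, 15 and 13) than rose (11 each), with the list still called upward.

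Division, progenitor and synthesis lists fell. All 20 S phase genes fell (camera adjusted p = 2.4e-09), which held at an adjusted p = 0.00804 with an estimated correlation. Mcm7 fell from 268 ± 1.04 to 1.43 ± 0.269 FPKM (log2 change -6.69, SE 0.09). All 20 G2 and M phase genes fell (camera adjusted p = 9.3e-09, adjusted p = 0.0913 with an estimated correlation), Cdc20 from 99.97 ± 2.62 to 0.343 ± 0.0416 FPKM (log2 change -7.34, SE 0.14) while Mki67 fell by 2.92 on the log2 scale (SE 0.13). Of 21 myeloid progenitor genes 17 fell and 3 rose (camera adjusted p = 1.5e-05), which held at an adjusted p = 0.0298 with an estimated correlation. The myeloperoxidase gene Mpo stood at 0.05 ± 0.0200 against 119 ± 11.7 FPKM. Of 19 cholesterol synthesis genes 15 fell and 1 rose (camera adjusted p = 7.9e-04, adjusted p = 0.451 with an estimated correlation), of 30 ribosomal protein genes 20 fell and 4 rose (camera adjusted p = 0.0104, adjusted p = 0.632 with an estimated correlation), and of 23 oxidative phosphorylation genes 13 fell and 5 rose (camera adjusted p = 0.0271, adjusted p = 0.393 with an estimated correlation).

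Between Hoxb8 macrophages and progenitor cells 9942 of 11793 genes (84.3%) passed edgeR's quasi-likelihood test, 5269 higher and 4673 lower in macrophages, with 5858 changed at least 2-fold. The FPKM values of the libraries did not overlap for 88.5% of genes, where chance without a scaling offset gives 10%. The split turned to 3045 higher and 7173 lower under FPKM, 2544 and 7848 under TPM, 3123 and 7195 under library totals, 4603 and 5365 under the upper quartile, and 4493 and 5410 after quantile normalisation. Of 33 lists 22 were called, 16 up and 6 down, and 4 of these calls held with an estimated correlation. The lysosome list was the only list of 35 with another number of calls adjusted over the list alone.

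**Figure D4:**
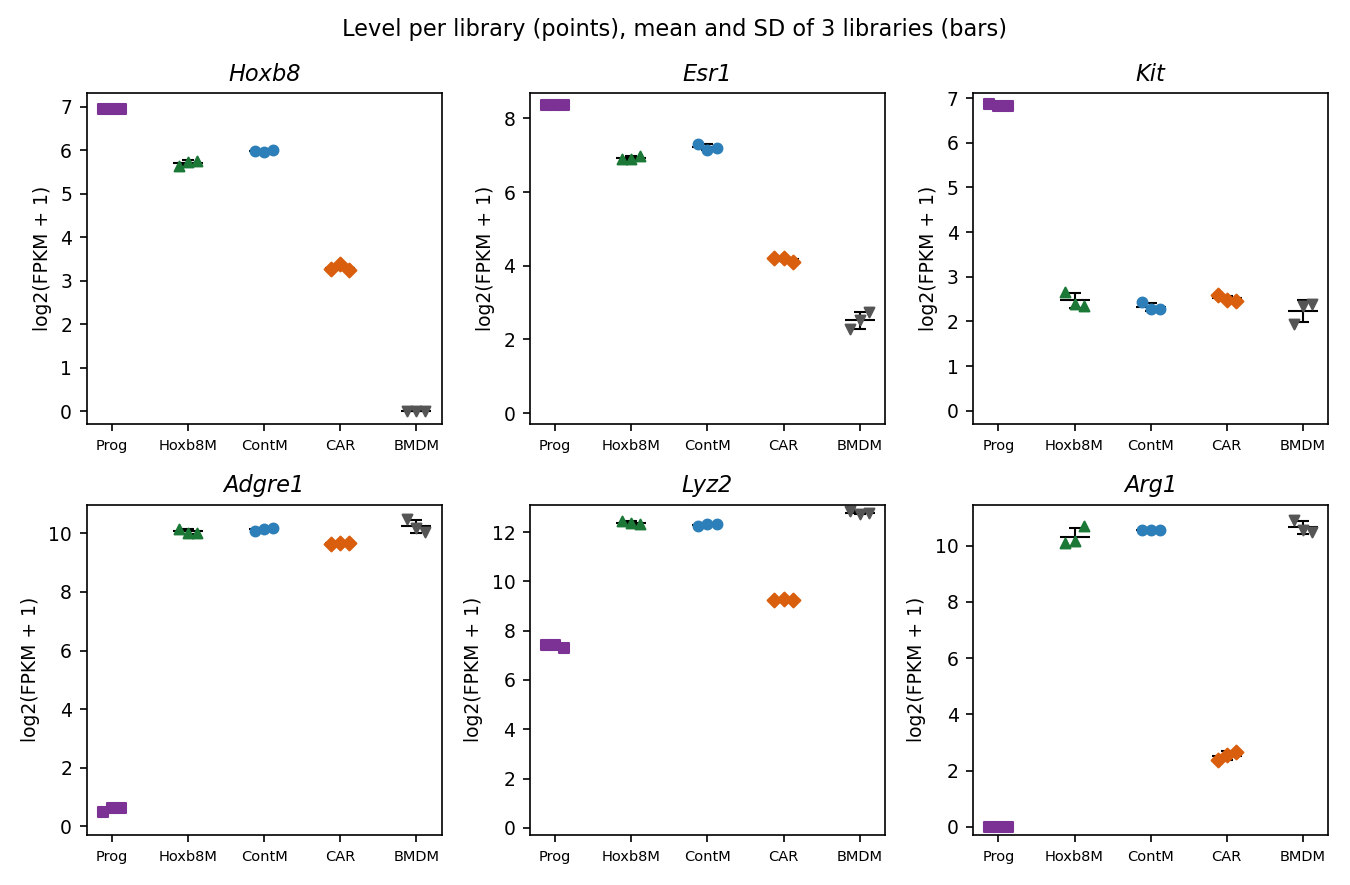
Levels of 6 genes in each library as log2(FPKM + 1), with a point per library and the mean and SD of 3 libraries per group. Hoxb8 falls from 122 FPKM in progenitor cells to 51.2 in Hoxb8 macrophages and 8.86 in CAR macrophages, with 0 in BMDM, and Arg1 is low in progenitor cells and CAR macrophages.

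BMDM were compared with the same progenitor cells as a reference macrophage. Whether the BMDM libraries also held other marrow cells was not tested, and differentiation was again not told apart from activation. Adgre1 rose to 1213 FPKM from 0.49 (log2 change 11.94, SE 0.17) and Lyz2 to 7072 from 165 FPKM (log2 change 6.10). Hoxb8 was 122 ± 0.830 FPKM in progenitors and had a count of 0 in the 3 BMDM libraries, at least 955-fold lower. Kit fell from 113 ± 1.31 to 3.73 FPKM (log2 change -4.26, SE 0.10), Cd34 by 2.90 and Mpo by 1.86 (SE 0.10) on the log2 scale. Mki67 was 34.8 against 79.3 FPKM, a log2 change of -0.54 (SE 0.11), for which edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 2.4e-04.

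Among the largest rises, Saa3 reached 10592 ± 980 FPKM against 0.04, and Thbs1, a secreted matrix glycoprotein, 4918 ± 363 FPKM from a count of 0, at least 254763-fold higher. Cxcl3 reached 6940 ± 320 FPKM, at least 46308-fold higher than progenitors at 0. S100a8 and S100a9, which form calprotectin, reached 4538 ± 2009 and 2988 ± 1189 FPKM, at least 4102-fold and at least 6133-fold higher. The largest falls besides Hoxb8 included Angpt1, a ligand of the vessel receptor TIE2 (0.24 against 107 FPKM, log2 change -8.14, SE 0.09), the collagen receptor gene Mrc2 (log2 change -8.49, SE 0.11), Emid1 (log2 change -7.75, SE 0.15) and Muc13 (log2 change -6.12).

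Of the 24 lists called in BMDM against progenitors, some are given here and others, including further cell type lists, are left out. All 24 pro-inflammatory genes rose (camera adjusted p = 9.6e-10), which held at an adjusted p = 0.0123 with an estimated correlation, and Nos2 reached 640.2 ± 48.6 FPKM, at least 23073-fold above progenitors at 0. Of 24 macrophage identity genes 23 rose and 1 fell (camera adjusted p = 1.3e-07, adjusted p = 0.0732 with an estimated correlation), with the complement gene C1qb at 63.1 ± 14.6 FPKM and a count of 0 in progenitors. The MHC class II list had 11 rises and 2 falls among 13 members (camera adjusted p = 0.00120, adjusted p = 0.169 with an estimated correlation), with the invariant chain gene Cd74 at 876 ± 22.9 against 0.253 FPKM. All 5 tested B cell genes rose (camera adjusted p = 0.0116, adjusted p = 0.169 with an estimated correlation). Of 13 inhibitory and checkpoint genes 12 rose and 1 fell (camera adjusted p = 3.3e-04), which held at an adjusted p = 0.0263 with an estimated correlation, Pirb from 0.35 to 146 ± 5.74 FPKM (log2 change 9.35, SE 0.08). All 20 S phase genes fell (camera adjusted p = 1.3e-07), which held at an adjusted p = 0.0123 with an estimated correlation, Mcm2 from 176 ± 4.60 to 10.9 ± 0.205 FPKM (log2 change -3.34, SE 0.07). All 20 G2 and M phase genes fell (camera adjusted p = 6.8e-05, adjusted p = 0.169 with an estimated correlation), Cdc20 from 99.97 ± 2.62 to 16.8 ± 1.89 FPKM (log2 change -1.90, SE 0.08). Of 21 myeloid progenitor genes 16 fell and 5 rose (camera adjusted p = 7.0e-04, adjusted p = 0.0560 with an estimated correlation). The ribosomal protein list fell, with 18 of 30 members lower and 3 higher over all genes and 17 and 3 adjusted over the list alone (camera adjusted p = 0.0107, adjusted p = 0.517 with an estimated correlation). It was the only list of 35 where these counts differed.

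Between BMDM and progenitor cells 10294 of 11793 genes (87.3%) passed edgeR's quasi-likelihood test, 5497 higher and 4797 lower in BMDM, with 5925 changed at least 2-fold. The FPKM values of the libraries did not overlap for 90.4% of genes, where chance without a scaling offset gives 10%. The split turned to 3694 higher and 6956 lower under FPKM, 3454 and 7271 under TPM, 3762 and 6959 under library totals, 4963 and 5425 under the upper quartile, and 4309 and 6135 after quantile normalisation. Of 33 lists 24 were called, 18 up and 6 down, of which 3 held with an estimated correlation. The adjusted p with an estimated correlation lay between 0.0560 and 0.517 for those that did not hold.

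BMDM and Hoxb8 macrophages were set against the same progenitor libraries, so their changes share chance values. Their log2 changes had a correlation of 0.822 and a covariance of 5.39 across 11793 genes, which are not independent replicates. In 100 simulations of unaltered groups against these progenitors, the mean correlation was 0.653 (highest 0.678) and the mean covariance 0.0252. The difference of the covariances was 5.37. In both comparisons 4457 genes rose, where independent lists would share 2456, and 4026 fell, where independent lists would share 1901, and 554 genes went opposite ways. With 3 progenitor libraries the controls could not be split into parts of at least 2, so part of the excess may come from the shared controls. The simulated groups were drawn around the mean of these same libraries, so the simulated covariance may understate that part. Any 2 groups that both differ from progenitors can share changes. The overlap beyond independent lists therefore does not show a likeness particular to these 2 groups.

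Hoxb8 macrophages were also compared with BMDM directly, macrophages of both kinds being wild type and untreated. Mpo, a myeloid progenitor gene, was 20.6 ± 4.63 FPKM in BMDM and 0.05 ± 0.0200 in Hoxb8 macrophages. Which cells of the BMDM libraries carried the progenitor, neutrophil, B cell, megakaryocyte and division genes was not tested. Adgre1 was 1070 ± 56.0 FPKM in Hoxb8 macrophages and 1213 FPKM in BMDM and did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (log2 change -0.02, adjusted p = 0.843), but was called lower under TPM (log2 change -0.35) and library totals (-0.19). Hoxb8 stood at 51.2 ± 2.04 FPKM in Hoxb8 macrophages and at a count of 0 in BMDM, at least 715-fold higher. Esr1 was 121 ± 4.30 against 4.78 FPKM (log2 change 3.75, SE 0.09). Its mean counts were 4171 and 373, which lie less far apart than the FPKM levels. Cdkn2a, a cell cycle inhibitor locus, was 83.4 ± 4.09 against 1.99 ± 0.633 FPKM (log2 change 5.50, SE 0.11). Cxcl1 had a count of 0 in Hoxb8 macrophages and 546 ± 23.4 FPKM in BMDM, at least 1881-fold lower.

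Hoxb8 macrophages also held more Hamp (3828 against 151 FPKM, log2 change 4.82, SE 0.19). They held less Ifitm1, an interferon-induced membrane protein (11.3 against 4271 FPKM, log2 change -8.31, SE 0.12), less of the membrane protease gene Mmp14 (0.637 ± 0.146 against 431 ± 26.7 FPKM, log2 change -9.24, SE 0.12) and less Tgfbi (1.5 against 620.03 FPKM, log2 change -8.52). The neuropeptide genes Cck and Npy, at 196 and 189 FPKM in BMDM, had counts of 0, at least 402-fold and at least 262-fold lower. H2-Aa, an MHC class II chain, stood at 0.117 against 171 FPKM. Nos2 was higher in Hoxb8 macrophages (1981 ± 178 against 640.2 ± 48.6 FPKM, log2 change 1.79, SE 0.10), and Cd86 (log2 change -7.01, SE 0.17) and Mrc1, the mannose receptor (log2 change -4.00, SE 0.22), were lower. In build GRCm38.p6, Cdkn2a (gene ID 12578) lies on chromosome 4 from 89274473 to 89294619 and Esr1 (13982) on chromosome 10 from 4611989 to 5005633.

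Division lists were lower in Hoxb8 macrophages than in BMDM. All 20 G2 and M phase genes were lower (camera adjusted p = 1.5e-09, adjusted p = 0.125 with an estimated correlation), with Cdc20 at 0.343 ± 0.0416 against 16.8 ± 1.89 FPKM (log2 change -5.43, SE 0.16) and Mki67 with a log2 change of -2.38 (SE 0.12). Of 20 S phase genes 18 fell and 1 rose (camera adjusted p = 7.5e-07), the call that held at an adjusted p = 0.0290 with an estimated correlation. Of 21 myeloid progenitor genes 15 fell and 4 rose (camera adjusted p = 0.00340, adjusted p = 0.125 with an estimated correlation), with the neutrophil elastase gene Elane at 0.123 against 77.4 FPKM. The neutrophil list had 15 falls and 2 rises (camera adjusted p = 2.7e-04, adjusted p = 0.231 with an estimated correlation).

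Macrophage identity and MHC class II lists were lower too. The macrophage identity list had 17 falls and 5 rises among 24 members, and 18 falls and 5 rises adjusted over the list alone (camera adjusted p = 0.00340, adjusted p = 0.294 with an estimated correlation). The complement gene C1qb was 0.490 ± 0.0557 against 63.1 ± 14.6 FPKM (log2 change -6.82, SE 0.25). Of 13 MHC class II genes 9 fell and 3 rose (camera adjusted p = 0.0221, adjusted p = 0.294 with an estimated correlation), with H2-Eb1 at 0.153 ± 0.0666 against 85.6 ± 1.25 FPKM (log2 change -8.94, SE 0.15). This call was lost under TPM (adjusted p = 0.0640) and library totals (0.0737). The MHC class I list had 5 rises and 6 falls among 14 and was not called (camera adjusted p = 0.712). All 5 tested B cell genes were lower (camera adjusted p = 8.0e-04, adjusted p = 0.125 with an estimated correlation), with Cd79b at 0 against 15.7 ± 3.61 FPKM. Of 21 interferon genes 16 fell and 4 rose (camera adjusted p = 0.00695, adjusted p = 0.287 with an estimated correlation), a call lost under TPM (0.0602). Matrix protease genes had 10 falls and 3 rises among 14 (camera adjusted p = 0.01, adjusted p = 0.294 with an estimated correlation), and phagocytosis genes 14 falls and 6 rises among 26 (camera adjusted p = 0.0221, adjusted p = 0.476 with an estimated correlation). Alternative activation genes had 13 falls and 2 rises among 19 (camera adjusted p = 0.0291, adjusted p = 0.294 with an estimated correlation), a call lost under TPM (0.0952) and library totals (0.0737). The dendritic cell list, with 7 falls and 1 rise among 9 (camera adjusted p = 0.0222, adjusted p = 0.125 with an estimated correlation), lost its call under TPM (0.0602) and library totals (0.0560). The fibroblast list, with 6 falls and 1 rise among 7 (camera adjusted p = 0.0132, adjusted p = 0.125 with an estimated correlation), lost it under FPKM (0.0509) and TPM (0.124). The megakaryocyte list had 5 falls and 1 rise (camera adjusted p = 0.0132, adjusted p = 0.125 with an estimated correlation), with the platelet chemokine gene Ppbp at 1.37 ± 0.289 against 165 ± 12.5 FPKM.

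The 5 lists that camera called higher in Hoxb8 macrophages were those of glycolysis, heat shock, inflammation, apoptosis and iron. The glycolysis and hypoxia list had 23 rises and 1 fall (camera adjusted p = 8.8e-09, adjusted p = 0.162 with an estimated correlation), with the angiogenic factor gene Vegfa at 462 ± 26.2 against 114 ± 20.3 FPKM (log2 change 2.17, SE 0.10). All 11 tested heat shock genes rose (camera adjusted p = 1.8e-04, adjusted p = 0.125 with an estimated correlation), with Hspa1b at 34.2 ± 4.88 against 1.11 ± 0.0777 FPKM (log2 change 5.10, SE 0.15), a gene whose near-identical copy Hspa1a makes its count uncertain. The pro-inflammatory list had 16 rises and 6 falls among 24 members, and 17 and 6 adjusted over the list alone (camera adjusted p = 0.0178, adjusted p = 0.231 with an estimated correlation, 0.339 after quantile normalisation). Its median log2 change was 0.65 and its mean -0.37. Camera called the list upward and fry called it downward (adjusted p = 7.4e-08), and why they differed was not tested. In this list Ccl5 was 18900 ± 1643 against 2303 ± 499 FPKM (log2 change 3.19, SE 0.14). Of 26 apoptosis and p53 genes 15 rose and 7 fell (camera adjusted p = 0.0221, adjusted p = 0.125 with an estimated correlation, 0.151 after quantile normalisation), while under TPM 11 rose and 12 fell. The cell cycle inhibitor gene Cdkn1a was 889 ± 53.3 against 310.1 ± 13.7 FPKM (log2 change 1.68, SE 0.06). Of 15 NRF2 and iron genes 12 rose and 3 fell (camera adjusted p = 0.0132, adjusted p = 0.294 with an estimated correlation), a call lost after quantile normalisation (0.368).

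Between Hoxb8 macrophages and BMDM 8292 of 11793 genes (70.3%) passed edgeR's quasi-likelihood test, 3776 higher and 4516 lower in Hoxb8 macrophages, with 2783 changed at least 2-fold. The FPKM values of the libraries did not overlap for 70.7% of genes, where chance without a scaling offset gives 10%. The split was 2617 higher and 5758 lower under FPKM, 1815 and 7172 under TPM, 2628 and 5865 under library totals, and 4869 and 3609 after quantile normalisation. Of 33 lists 19 were called, 5 up and 14 down, and the adjusted p with an estimated correlation was 0.125 to 0.476 for the 18 others than S phase. The number of calls adjusted over the list alone differed for 4 of 35 lists.

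Control-CAR macrophages differed little from untreated Hoxb8 macrophages. Rtn4rl2, a receptor of the Nogo family, fell from 10.3 ± 1.62 to 2.07 ± 0.352 FPKM (SD, n = 3), a log2 change of -2.40 (SE 0.14). Rbm3, a cold-induced RNA-binding protein, rose from 81.5 ± 2.22 to 115 ± 8.51 FPKM, a log2 change of 0.43 (SE 0.06). The sphingosine phosphate receptor gene S1pr3 fell by 1.01 (SE 0.09) and the metalloprotease gene Amz1 by 1.07 (SE 0.10) on the log2 scale. Hspa1b fell from 34.2 ± 4.88 to 19 ± 3.56 FPKM (log2 change -0.89, SE 0.11). The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 2.2e-08 for Rtn4rl2, 6.1e-04 for Rbm3, 1.8e-05 for Amz1 and 2.2e-04 for Hspa1b. Smaller changes among the named genes included Aldh1l2 and Lrrc32 (log2 changes -0.85 and -0.87, SE 0.10 each) and Abhd2 (log2 change 0.39, SE 0.07). Adgre1, Csf1r, Lyz2, Kit, Arg1, Nos2, Il1b and Tnf did not pass the test. In build GRCm38.p6, Rtn4rl2 (gene ID 269295) lies on chromosome 2 from 84871297 to 84888641 and Rbm3 (19652) on chromosome X from 8138975 to 8145880.

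Of the fixed genes, Hoxb8 was 61.9 ± 1.0 FPKM in control-CAR and 51.2 ± 2.04 FPKM in Hoxb8 macrophages (log2 change 0.23, SE 0.05). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave Hoxb8 an adjusted p of 0.0265, which rose past the threshold without control-CAR replicate 2 (0.0620) or 3 (0.114) and without Hoxb8 macrophage replicate 1 (0.131) or 2 (0.0574).

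Of 33 lists 5 were called in this comparison, and none of the 5 held with an estimated correlation. Of 11 tested heat shock genes 3 fell, and 4 adjusted over the list alone (camera adjusted p = 4.6e-04, adjusted p = 0.554 with an estimated correlation), among them the chaperonin gene Hspe1 (log2 change -0.46, SE 0.08). The ribosomal protein list shifted down with 0 of 30 members called, and 16 falls adjusted over the list alone (camera adjusted p = 1.0e-10, adjusted p = 0.554 with an estimated correlation). The glycolysis and hypoxia list shifted down with 0 of 24 called, and 8 falls adjusted over the list alone (camera adjusted p = 3.3e-05, adjusted p = 0.554 with an estimated correlation). The neutrophil list shifted up with 0 of 17 called, and 2 rises adjusted over the list alone (camera adjusted p = 0.00155, adjusted p = 0.554 with an estimated correlation). The NRF2 and iron list shifted up with 1 of 15 called, the glutathione synthesis gene Gclm, and 4 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.0185, adjusted p = 0.585 with an estimated correlation). The number of lists called was 13 without control-CAR replicate 2, 9 without control-CAR replicate 3 and 11 without Hoxb8 macrophage replicate 3.

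Between control-CAR and Hoxb8 macrophages 309 of 11793 genes (2.62%) passed edgeR's quasi-likelihood test, 85 higher and 224 lower in control-CAR macrophages, with 20 changed at least 2-fold. At an unadjusted p under 0.05 there were 2128 genes. The FPKM values of the libraries did not overlap for 21.9% of genes, where chance without a scaling offset gives 10%. The number of called genes rested on single libraries, with 118 without control-CAR replicate 3, and 106 and 170 without Hoxb8 macrophage replicates 1 and 2. It was 97 with only these 6 libraries in the model and 470 under library totals. The full model shares 1 estimate of the spread per gene over all 5 groups. The chi-square per degree of freedom of library pairs was 2.96 to 15.3 in control-CAR and 4.82 to 8.44 in Hoxb8 macrophages. It was 1.40 to 2.01 in CAR macrophages, 2.05 to 3.45 in progenitors and 6.63 to 21.3 in BMDM. The split turned to 248 higher and 157 lower under FPKM, 310 and 147 under TPM, and 278 and 192 under library totals.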

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

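The tests with DESeq2, with its size factors in edgeR and with library totals were chosen only after the data were seen, as were the counts over other splits. The counts of called genes and lists stayed within 1.5 times of the reported ones under each alternative, except as follows. A 2-fold minimum, a stricter call by construction, left 3739 genes for CAR against control-CAR macrophages, 5858 for Hoxb8 macrophages against progenitors, 2783 for Hoxb8 macrophages against BMDM, 20 for control-CAR against Hoxb8 macrophages and 5925 for BMDM against progenitors. With an estimated correlation, camera called 1, 4, 1, 0 and 3 lists in the same order, against 10, 22, 19, 5 and 24 at the preset correlation, and the cause was not tested. fry, which asks whether a list moves by itself, called 28 lists for CAR against control-CAR, 30 for Hoxb8 macrophages against BMDM and 1 for control-CAR against Hoxb8 macrophages. Fits of only the 6 libraries compared have fewer residual degrees of freedom and their own estimate of the spread. They called 9334, 10107, 7626 and 10188 genes in the other comparisons, in the same order. In control-CAR against Hoxb8 macrophages such a fit called 97 genes, and the cause of this drop was not tested. Under library totals 470 were called, against 309, and that setting differs from the reported fit only in leaving out the TMM factors. Leaving out 1 library at a time gave 106 to 311 genes and 4 to 13 lists there. The correlation of the changes in BMDM and Hoxb8 macrophages against progenitors was 0.898 on log2 FPKM with a pseudocount of 5 (0.851 with 0.1), against 0.822 on log2 CPM, so both the measure and the pseudocount differ, and the cause was not tested.

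Over the alternatives, 4784 results of named genes kept their side of the threshold. Those called in both the reported fit and the alternative also kept their direction. For results called in neither fit the direction was not compared. A further 80 lost the call and 19 gained it with the same direction. Another 6 turned, counted only where the reported fit or the alternative passed the threshold. On the log2 scale, the direction turned for Cd68 in CAR against control-CAR macrophages under TPM (0.22) and quantile normalisation (0.084), for Ctsd after quantile normalisation (0.27), for Kit under TPM (0.40), for Mpo after quantile normalisation (-0.16), and for Il1b in Hoxb8 macrophages against BMDM after quantile normalisation (-0.14), and the cause was not tested.

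Genes at a count of 0 in a group carry lower bounds for their folds, and the floor of 3 counts per library limits them. The groups share replicate numbers. Deviations of same-numbered libraries had 15 correlations from -0.144 to 0.0312, so the numbers did not pair the samples. With the replicate number as a block, 9204, 9889, 8159, 246 and 10246 genes were called, and 10, 22, 19, 5 and 24 lists, none over 1.5 times from the counts without the block. Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in each comparison. The real splits called 9280, 9942, 8292, 309 and 10294 genes and the highest other splits 1, 0, 1, 1 and 0. Each other split mixes libraries of both groups, which turns any group difference into spread. Their low counts were therefore fixed in advance and lend no support.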

Other observations

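All tests of explanations in this part were chosen only after the result was seen.

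Single genes differed between CAR and control-CAR macrophages in lists that camera did not call. Timp1, an inhibitor of matrix proteases, rose from 4.64 ± 1.03 to 157 ± 1.54 FPKM (SD, n = 3; log2 change 4.77, SE 0.12), and the gelatinase gene Mmp2 from 0.69 ± 0.0964 to 17.4 ± 0.663 FPKM (log2 change 4.35, SE 0.13). Of 14 tested matrix protease genes 9 rose and 5 fell (camera adjusted p = 0.523). The serine synthesis enzymes Phgdh and Psat1 rose, Phgdh from 15.5 ± 2.59 to 151 ± 3.18 FPKM (log2 change 2.99, SE 0.13) and Psat1 with a log2 change of 1.85 (SE 0.10), in a stress list with 10 rises and 6 falls among 20 members (camera adjusted p = 0.600). The immunoregulatory cytokine gene Il10 rose from 1.25 ± 0.167 to 18.5 ± 0.928 FPKM (log2 change 3.59, SE 0.18) while the chitinase-like gene Chil3 fell from 899 ± 47.2 to 154 ± 3.39 FPKM (log2 change -2.85, SE 0.14), in an alternative activation list with 8 rises and 9 falls among 19 (8 and 5 under FPKM, camera adjusted p = 0.389). The inhibitory receptor genes Vsir and Siglece fell, with log2 changes of -3.05 (SE 0.07) and -2.53 (SE 0.07), in a list with 4 rises and 7 falls among 13 (7 and 4 under TPM, camera adjusted p = 0.192). Monocyte genes went both ways, with 6 rises and 7 falls among 13 (camera adjusted p = 0.523), Ly6c2 falling from 358 ± 33.1 to 24.6 ± 1.31 FPKM and the fibronectin gene Fn1 at 44.4 ± 0.991 against 0.0167 ± 0.00577 FPKM.

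Mast cell and basophil genes and 5 of 7 tested fibroblast genes were higher in the CAR libraries. Progenitor cells left in the CAR culture were argued against as the only source of the mast cell and basophil genes. Of the 9 tested, 8 lay above their progenitor level in every CAR library. The fibroblast genes were not set against progenitor levels, and such cells may still supply part of the pattern. Mast cells or basophils among the CAR cells may account for part of it and stay open. Kit, taken as the receptor of mast cells, had a change of -0.078 on the log2 scale (0.40 under TPM, -0.38 after quantile normalisation). No library of mast cells sets a bound for it, and Kit was not a test for basophils. Tpsb2 was 329, Mcpt8 222 and Hdc 681 FPKM, with Hdc at 396 FPKM in control-CAR macrophages and Gata2 shared with the progenitor list. Fibroblast-like cells among the CAR cells also stay open, with Col1a1 at 1.5 FPKM beside Col1a2 at 23.9, Col3a1 at 0.143 and Pdgfra at 0.78 FPKM. The CAR treatment itself remains untested as the biological explanation, and no sort or gate is given in the labels.

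Hoxb8 and Esr1 were lower in the CAR libraries. A dilution by cells without macrophage genes was argued against as the only cause of the fall of Hoxb8. Of the 24 tested macrophage identity genes, 21 rose or fell less than Hoxb8 by over 2 SE. A partial dilution stays open, because the test asked only whether these genes fell as far as Hoxb8. Library scaling was argued against too, since the smallest fall of Hoxb8 over the scaling alternatives was -2.48 on the log2 scale. A dilution by macrophages that carry no Hoxb8 construct stays open, as Esr1 changed by -3.28 beside -3.11 for Hoxb8. BMDM, with a Hoxb8 count of 0, correlated with CAR macrophages at 0.807 across genes, and control-CAR macrophages did so at 0.80. Cxcl1 and Cd86, higher in CAR than in control-CAR macrophages, stood at 546 and 31.5 FPKM in BMDM. Arg1, lower in CAR macrophages, went the other way, at 1624 FPKM in BMDM. How many of the CAR changes BMDM share was not counted. Weaker transcription of a construct that joins Hoxb8 to part of the estrogen receptor, a common design that the labels do not state, may give the same pair of falls and was not tested apart.

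Hoxb8 was still present in Hoxb8 macrophages, at 42.0% of its progenitor FPKM, while under TMM the log2 change was -0.42. Progenitor cells left among the macrophages were argued against, because 17 of the 21 tested myeloid progenitor genes lay below 42.0% of their own progenitor FPKM in every library, with Kit at 4.03% and Ctsg at 0.0919%, and a scaling factor common to all genes moves each share alike. Ordinary activity of the Hoxb8 gene in macrophages was argued against by a summed count of 0 in the 3 BMDM libraries. No biological explanation was tested, and transcription of an introduced Hoxb8 may be the source.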
